A study of Mus musculus with 2 samples.

How the data were processed

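Gene expression was measured by RNA sequencing in 2 libraries of sorted mouse bone marrow cells, 1 library from control mice and 1 from mice with an inducible JAK2 V617F transgene. Per the labels, each library was made from cells pooled from 3 animals of 1 genotype, so there was 1 sample per group. Per the labels' protocols, 2-3 ng of RNA was amplified to cDNA with the Ovation RNA-Seq System v2 (NuGEN), the cDNA was sonicated, and libraries were prepared with a TruSeq DNA kit and sequenced on a Genome Analyzer IIx. No molecular identifiers are mentioned, so reads copied in amplification could not be told from separate molecules.

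The deposited table gives 1 FPKM value (fragments scaled by transcript length and by the number of mapped fragments) per gene and library, as computed by the authors. Per the submitters' processing notes, cutadapt 1.2.1, TopHat2 2.0.7, Bowtie2 2.0.6 and Cufflinks were used with mouse build GRCm38. The annotation release, the use of strand, any between-library scaling and the Cufflinks settings are not given in the sources used here. The table has 35798 rows, each with a Cufflinks gene identifier, a gene symbol and a locus. A locus start counts from 0 in the table and from 1 here, and a locus can span several overlapping genes. Of the rows, 401 name several genes at once, and list members that occur only in such rows were left out. Symbols were matched to GENCODE vM21 (77.0% of rows) and, for gene type, to a RefSeq table of GRCm38.p6 that includes synonyms, which gave 20039 protein-coding genes with a row of their own. A further 3719 rows were taken as small RNAs from their symbols. Mitochondrially encoded genes were on a planned list but were not analysed here.

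FPKM values are not counts, and with 1 library per group no test between genotypes can be made. No p-value between the groups is given. For each gene, log2((JAK2 V617F FPKM + 1)/(control FPKM + 1)) was computed. Fold thresholds refer to this scale, which understates the change of low genes. Genes at 1 FPKM or more in at least 1 library were kept, and a gene was called higher or lower in the JAK2 V617F library at a difference of at least 2-fold (1 on the log2 scale). Such a call describes 2 pools of cells and has no replicate check.

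The depth of each library was estimated from the values. For 5601 genes with 1 annotated transcript and the same locus in GENCODE vM21, FPKM was multiplied by transcript length minus 170 nt, an offset picked from 31 values between 0 and 300 nt as the one that made the lowest step sharpest, so the sharpness of that step is not independent evidence. The products fell into steps. A single fragment was worth 0.182 FPKM at 1 kb of effective length in the control library and 0.157 in the JAK2 V617F library. Of the genes below 3.5 estimated fragments, 81.2% and 82.2% lay within 0.2 of a whole number, where evenly spread values would give 40%. The value of 1 fragment was set from the lowest step of these same genes, 152 in the control and 279 in the JAK2 V617F library. Those genes are centred near 1 fragment by construction, so the 40% is no baseline for them. The steps put the FPKM denominators at about 5500000 and 6360000 fragments. On a transcript of 2 kb, 1 fragment was worth 0.0994 FPKM in the control library and 0.0859 in the JAK2 V617F library. For genes with a single transcript, the estimated fragments gave an exact (Clopper-Pearson) 95% interval for the ratio. These intervals are approximate and cover counting error only. For other genes the depth per gene is unknown.

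The 35 gene lists for niche function, differentiation, nerve, signalling, RNA quality and other cell types were fixed before the data were examined, as were the pseudocount, the filters and the main alternatives. Of their 543 entries, 516 had a row of their own and 441 reached 1 FPKM. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size. Random members were drawn from protein-coding genes in 20 bins of mean expression. This pool, and leaving out members that share a row, were chosen after seeing the data, and drawing from all rows and including shared rows were run as alternatives. This position describes the 2 libraries and is not a test of the conditions. With 34 lists placed, about 1.7 would lie outside the central 95% by chance if list members varied independently. Genes of 1 cell type or pathway can vary together between any pools, so this number is no baseline for these lists. Genes were named by a rule fixed at the same time. It took Jak2, Nes, all niche factors, the 4 members of each list with the largest change, and the highest rows of each library. It also took the 10 genes with the largest increase and the 10 with the largest decrease. These 20 had to reach 5 FPKM in a library and have an official symbol with 1 row. Symbols of the Gm and Rik kinds, those beginning with Mir, Snor, Rn or n-R and those containing -ps were left out, and other small RNAs, such as the Scarna class, were not. The values of some members that this rule takes are not reported here. Further members of a list are named as examples, and these were chosen after their values were seen.

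The list placement was tested on simulated data, with the ratios of the 12477 protein-coding genes shuffled within expression bins. Of 200 lists of 15 genes with no effect, 3.0% lay outside the central 95%. The shuffle removes any tendency of list members to vary together, so this rate holds for independent genes only. Lists shifted by 0.25, 0.5 and 1.0 on the log2 scale were placed above it in 27%, 70% and 100% of 100 draws. For 200 genes with a mean of at least 20 FPKM multiplied by a known fold of 2 or 4, 39.5% and 94.0% were called at least 2-fold higher. The alternatives were a pseudocount of 0.1 or 5, 4 other scalings, other filters, a 4-fold threshold and other list memberships. Restricting counts to protein-coding genes, the depth estimate and 3 further lists of cartilage and oligodendrocyte genes were also added after seeing the data. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.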

Results

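RNA was sequenced from bone marrow cells sorted as negative for CD45, CD31 and Ter119 (markers of leukocytes, endothelium and red cells) and positive for GFP driven by nestin regulatory sequence, a reporter of perivascular mesenchymal stromal cells of the haematopoietic stem cell niche. The control library came from Nes-gfp littermates. The other library came from Nes-gfp mice that also carried Mx1-cre and JAK2 V617F, the activating kinase mutation of myeloproliferative neoplasms. The labels give neither for the control, so an effect of Cre cannot be told from one of the mutation. Both libraries were collected 6 weeks after pIpC, a double-stranded RNA analogue that switches on Mx1-cre through interferon. Each library pooled 3 animals, and there was 1 library per genotype (n = 1). The values below therefore have no replicate error, and every difference is one between 2 pools. The estimated depth was about 5500000 fragments for the control library and about 6360000 for the JAK2 V617F library. The control library had 16913 rows above 0 FPKM and the JAK2 V617F library had 18883.

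The comparison asks how the transcriptome of the nestin-GFP+ niche cell differs in mice with the JAK2 V617F neoplasm. Jak2 itself was at 24.5 FPKM in the control and 29.9 FPKM in the JAK2 V617F library (log2 ratio 0.28). The transgene has no row of its own, so this value does not test the genotype label. Nes, whose promoter drives the sorting reporter, was low in both, at 4.84 and 3.00 FPKM (log2 ratio -0.55). Stromal identity transcripts were present in both libraries, most of them within 2-fold. Lepr, the leptin receptor, was at 84.8 FPKM in the control and 65.4 in the JAK2 V617F library. Ebf1, a stromal and B-lineage transcription factor, was at 58.3 and 58.7 FPKM. Pdgfrb was at 38.9 and 43.9 FPKM. Pdgfra was at 18.9 and 11.6 FPKM (-0.65) and Ebf3 at 54.7 and 34.0 FPKM (-0.67). On the whole list, 10 members lay below 0 and 7 above. Of the 17 measured mesenchymal stromal markers, 14 were within 2-fold, 1 was higher in the JAK2 V617F library (Mcam, 4.64 to 15.7 FPKM) and 2 were lower (Itgav, 47.5 to 15.3 FPKM, and Ly6a, 16.8 to 6.70 FPKM). Thy1 was at 9.79 and 20.1 FPKM, and past 2-fold under the 3 other scalings. The median log2 ratio of the list was -0.19, inside the central 95% of matched random lists (-0.39 to 0.27).

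The 12 measured factors by which stromal cells maintain haematopoietic stem cells did not shift as a group. Their median log2 ratio was -0.04, 6 members were above 0 and 6 below, and the central 95% of random lists was -0.43 to 0.25. Cxcl12, the main retention chemokine of stem cells, was at 891 FPKM in the control and 694 FPKM in the JAK2 V617F library (log2 ratio -0.36). Kitl, which encodes stem cell factor, was at 23.7 and 20.1 FPKM (-0.23). Angpt1 was at 10.2 and 7.5 FPKM (-0.39), and Vcam1 at 43.8 and 51.5 FPKM (0.23). Spp1, which encodes osteopontin and is also an osteoblast product, was at 2311 and 1201 FPKM (-0.94). Csf1 was at 47.8 and 28.1 FPKM (-0.75). Igf1 was the only member past 2-fold, at 10.8 FPKM in the control and 32.8 FPKM in the JAK2 V617F library (1.52). Jag1 was at 7.71 and 15.3 FPKM (0.90, and past 2-fold once both libraries were rescaled to the same sum), and Il7 at 2.15 and 4.34 FPKM (0.76). Ptn was at 6.40 and 8.56 FPKM, Bmp4 at 33.8 and 34.1 FPKM, and Tgfb1 at 40 and 37.2 FPKM. Thpo stayed below 1 FPKM in both libraries.

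Osteoblast-lineage and matrix transcripts were lower in the JAK2 V617F library. Of 17 osteoblast genes, 5 were at least 2-fold lower, none was 2-fold higher, and 16 had a ratio below 1. The median log2 ratio was -0.89, and 0 of the 10000 matched random lists had a lower median. Dmp1, a gene of late osteoblasts and osteocytes, was at 108 FPKM in the control and 28.3 FPKM in the JAK2 V617F library (log2 ratio -1.89). Bglap, which encodes osteocalcin and has the near-identical copy Bglap2, was at 519 and 171 FPKM (-1.60). Ifitm5 was at 45.3 and 15.8 FPKM (-1.46), and Sp7, the osteoblast transcription factor osterix, at 32.9 and 13.9 FPKM (-1.19). The bone collagen genes Col1a1 (2784 and 1436 FPKM) and Col1a2 (1955 and 978 FPKM) were lower by close to 2-fold. Ibsp, with about 3159 and 2504 estimated fragments, had a ratio of 0.685 with a counting interval of 0.65 to 0.722. Alpl alone lay above 0, at 36.2 and 40.4 FPKM. In the matrix and fibrosis list, 4 of 20 genes were at least 2-fold lower and none higher, with a median log2 ratio of -0.71 and 0 of 10000 random lists lower. These were the protease inhibitor Timp1 (76.9 to 28.2 FPKM), the collagenase Mmp13 (378 to 144 FPKM), Mmp2 (61.4 to 25.1 FPKM) and Lum (119 to 56.1 FPKM). Lum was within 2-fold under the 3 other scalings at which single genes were computed. Fn1 was at 60.2 and 60.3 FPKM. Pan-leukocyte transcripts were higher and erythroid transcripts lower in the same JAK2 V617F library, as given below.

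Cartilage transcripts were higher in the JAK2 V617F library. Of 15 measured chondrocyte genes, 9 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.07 that lay above all 10000 matched random lists. Prg4, which encodes the joint lubricant lubricin, went from 20.1 FPKM in the control library to 1234 FPKM in the JAK2 V617F library (log2 ratio 5.87). Its locus on chromosome 1 (150361305 to 150466165, GRCm38) also holds Tpr and BC003331. Matn3 was at 0.333 and 8.14 FPKM, from about 5 and 147 estimated fragments, a ratio of 25.4 with a counting interval of 10.6 to 79.4. Col10a1, the collagen of hypertrophic chondrocytes, was at 1.60 and 9.85 FPKM. Comp was at 9.19 and 39.5 FPKM, and Chad at 102 and 313 FPKM. Sox9, the transcription factor of the chondrocyte lineage, was at 3.11 and 7.41 FPKM, a ratio of 2.38 with a counting interval of 1.79 to 3.18. Also higher were Col9a1 (3.11 to 10.6 FPKM) and Hapln1 (7.83 to 17.5 FPKM). Within 2-fold, Col2a1 was at 178 and 238 FPKM, Acan at 17.7 and 20 FPKM, and Col11a1 at 146 and 117 FPKM. Ihh was at 1.24 FPKM in the control and was listed at 0 in the JAK2 V617F library. The adipocyte list had a median log2 ratio of 0.09, inside the random range. In it the adipogenic factors Pparg (1.33 and 4.78 FPKM) and Cebpd (6.86 and 18.5 FPKM) were higher, while Cebpb was at 2.84 and 4.73 FPKM, Cebpa at 4.61 and 2.80 FPKM, and Adipoq at 31.4 and 38.5 FPKM.

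**Figure D1:**
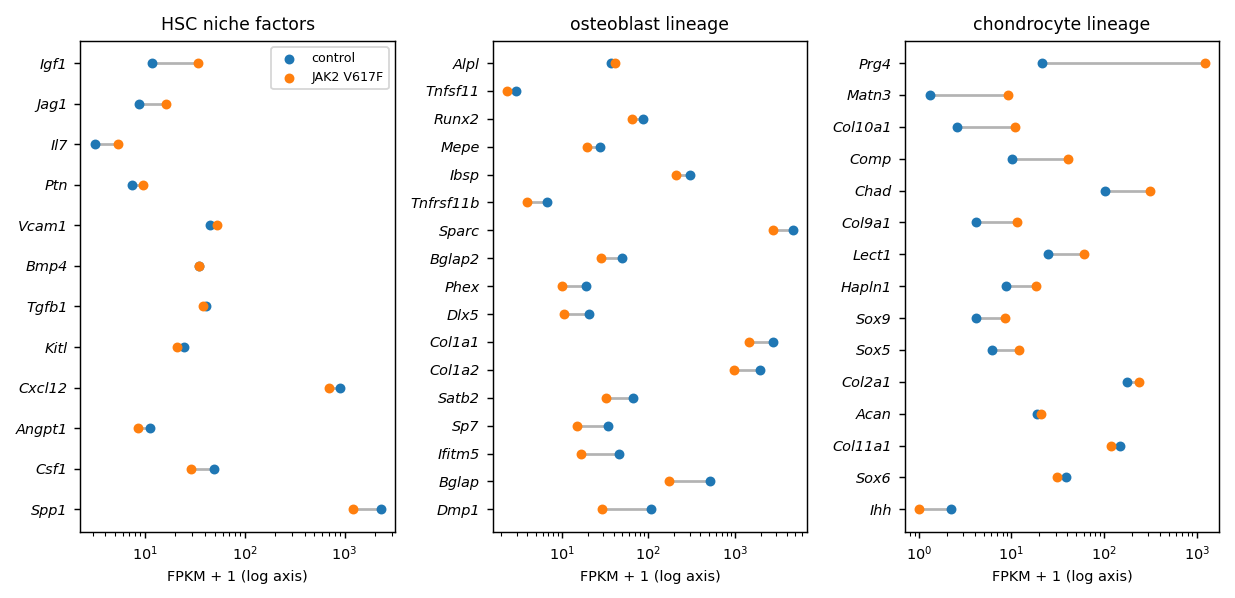
FPKM + 1 (log axis) of each measured member of 3 gene lists in the control library (blue) and the JAK2 V617F library (orange), 1 library each and no error bars. Of 12 niche factors, 6 are higher and 6 lower, 16 of 17 osteoblast genes are lower in the JAK2 V617F library, and 12 of 15 chondrocyte genes are higher, with Prg4 the farthest apart.

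Nerve-related transcripts were examined because the series concerns neuropathy of the niche. Of 15 Schwann and glial genes, 4 were at least 2-fold higher in the JAK2 V617F library and none lower. The median log2 ratio was 0.46, inside the random range (-0.42 to 0.50), but it lay above its range with a pseudocount of 0.1 (0.78), at 5 FPKM or more (0.75) and after rescaling without abundant classes (0.71). Mbp, a myelin gene that is also transcribed in blood cells, was at 624 FPKM in the control and 4872 FPKM in the JAK2 V617F library (2.96). S100b was at 22.4 and 76.2 FPKM (1.72). Pou3f1 and Gap43 were listed at 0 in the control and were at 1.26 and 1.11 FPKM in the JAK2 V617F library. The Schwann identity factor Sox10 was at 2.30 FPKM in both. Of 8 neuronal genes at 1 FPKM or more, 6 were at least 2-fold higher and 1, Sox2 (3.43 to 0.66 FPKM), was lower. The list's median of 1.46 lay above the random range (-0.71 to 1.11). Snap25, Syt1, Nefm and Prph were listed at 0 in the control library and were at 6.63, 3.72, 2.28 and 1.76 FPKM in the JAK2 V617F library. The neuronal median lay inside the random range with genes at 0 left out (0.24) and with no filter (0.36). Among neurotrophins and guidance cues (median 0.19), Slit2, a guidance ligand, was lower, from 124 to 43.6 FPKM. Sema3a was at 0.727 and 2.27 FPKM, Efnb2 at 2.93 and 4.81 FPKM, and Nrp2 at 71.5 and 49.8 FPKM. Of the adrenergic and cholinergic receptors, 5 reached 1 FPKM, with a median of 0.91 inside the random range. The β3-adrenergic receptor gene Adrb3 was listed at 0 in the control and at 0.345 FPKM in the JAK2 V617F library. Adra1b was at 0.147 and 1.25 FPKM, Adra1d at 0.733 and 2.25 FPKM, and Chrna4 was listed at 0 in the control and at 1.2 FPKM.

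The signalling lists of this paragraph lay inside their random ranges on the deposited scale. The inflammatory list lay below its range at 5 FPKM or more (-0.77), and the BMP, TGF-beta and Wnt list with a pseudocount of 0.1 (-0.41). Neither has a stable sign, since the inflammatory median was 0.20 with no filter and the BMP, TGF-beta and Wnt median 0.09 at 5 FPKM or more, both inside the range. Among 14 JAK-STAT targets, whose median log2 ratio was 0.07, 3 were at least 2-fold higher and 3 lower. Socs2 (3.07 to 14.9 FPKM), Cish (0.530 to 4.78 FPKM) and the kinase gene Pim2 (0.468 to 5.01 FPKM) were higher. Socs1 (5.55 to 0.285 FPKM), Pim1 (5.19 to 2.01 FPKM) and Bcl2l1 (12.3 to 5.21 FPKM) were lower. The type I interferon list had a median of -0.06. Rsad2 (23.2 to 8.24 FPKM), Irf7 (23.9 to 9.32 FPKM) and Oasl2 (18.7 to 7.52 FPKM) were lower, and Mx1 (0.438 to 2.79 FPKM) was higher. Among 12 inflammatory genes (median -0.41), 3 were at least 2-fold higher and 3 lower. The chemokines Ccl2 (12.0 to 1.17 FPKM) and Ccl3 (15.5 to 2.38 FPKM) were lower and Cxcl2 (0.434 to 9.87 FPKM) and Nfkbia (1.72 to 6.44 FPKM) were higher. Il1b was at 1.72 and 4.33 FPKM. Of 15 pro-apoptotic and p53 target genes (median -0.21), Fas alone passed 2-fold (0.730 to 2.98 FPKM). Apaf1 was at 26.7 and 13.9 FPKM, Cdkn1a at 119 and 65.8 FPKM, and Mdm2 at 31.6 and 49.2 FPKM. All 19 cell-cycle genes had ratios below 1 on the deposited scale, with a median of -0.22, and 5 of them lay above 1 after rescaling both libraries to the same sum. Ccnb2 (206 to 91.4 FPKM) was past 2-fold on the deposited scale and within it after that rescaling. Cdk1 was at 160 and 99.0 FPKM, Bub1 at 47.6 and 31.7 FPKM, and Ccna2 at 287 and 207 FPKM. In the list of BMP, TGF-beta and Wnt genes (median -0.29), 2 of 20 were at least 2-fold higher and 3 lower. Id1 was higher (2.55 to 17.4 FPKM), and Lef1 (8.83 to 2.19 FPKM), Bmp2 (14.3 to 4.30 FPKM) and Sfrp1 (6.20 to 1.71 FPKM) were lower.

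Metabolic, stress and immune-effector lists also lay inside their random ranges on the deposited scale. The unfolded protein response list lay above its range with a pseudocount of 5 (0.19) and at 5 FPKM or more (0.22). The immediate early list lay above with a pseudocount of 5 (0.24), with no filter (0.27) and without shared markers and the gene of largest change (0.31). Antigen presentation genes had a median log2 ratio of 0.26, with Cd74 (4.32 to 19.5 FPKM) and Tap2 (5.20 to 16.7 FPKM) higher, Nlrc5 (7.54 to 3.10 FPKM) lower, and H2-Ab1 at 6.71 and 14.4 FPKM. The call for Nlrc5 was lost under the 3 other scalings. Complement genes had a median of -0.00, with C1s (20.5 to 47.6 FPKM) higher, Cfp (15.3 to 5.50 FPKM) lower, and C3 at 42.7 and 63.8 FPKM. Glycolysis and hypoxia genes had a median of 0.00, with Ankrd37 (0.739 to 4.76 FPKM) and Egln3 (0.836 to 3.65 FPKM) higher, Car9 (2.86 to 0.798 FPKM) lower and Pdk1 at 27.8 and 18.9 FPKM. Cholesterol synthesis genes had a median of -0.13, with Mvd (4.05 to 1.21 FPKM) and Sc4mol (24.2 to 10.8 FPKM) lower, and Insig1 at 8.98 and 15.8 FPKM. The call for Sc4mol was lost after rescaling to the same sum. None of the 12 measured genes of the unfolded protein response passed 2-fold (median 0.20). Sdf2l1 was at 31.5 and 51.5 FPKM, Hspa5 at 249 and 383 FPKM, Herpud1 at 15.7 and 23.3 FPKM, and Atf4 at 184 and 116 FPKM. Immediate early genes had a median of 0.27, with Junb (37.1 to 15.1 FPKM) lower, Fosb (8.73 to 18.5 FPKM) higher, Dusp1 at 30.1 and 61.1 FPKM, and Klf2 at 5.13 and 10.5 FPKM. None of the 25 ribosomal protein genes passed 2-fold (median -0.02), and 10 of them lay above 0 on the deposited scale against 20 after rescaling to the same sum. The farthest from 0 were Rpl37 (236 and 327 FPKM), Rpl11 (923 and 712 FPKM), Rps14 (735 and 571 FPKM) and Rpl3 (435 and 341 FPKM).

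Transcripts of blood cells were abundant in both sorted pools and differed between them. The median erythroid gene was at 250 FPKM in the control and 162 FPKM in the JAK2 V617F library. Of 14 erythroid genes, 13 had a ratio below 1, with a median log2 ratio of -0.44 below the random range (-0.38 to 0.09). Without shared markers and the gene of largest change, the erythroid median was -0.39 and inside its range. The globin genes Hbb-b1 (1096 to 379 FPKM), Hbb-b2 (442 to 170 FPKM) and Hba-a1 (159 to 71.8 FPKM) were at least 2-fold lower. These genes have near-identical copies, Hba-a2 was at 28.6 and 52.8 FPKM, and the call for Hba-a1 was lost after rescaling to the same sum. Slc4a1 was at 380 and 195 FPKM. Neutrophil genes, with medians of 79.3 and 63.7 FPKM, had a median log2 ratio of 0.11, inside the range, and of 0.20, above it, with no filter or without shared markers and the gene of largest change. Of 14, 1 was at least 2-fold higher, Mmp8 (2.59 to 13.1 FPKM), and 4 were lower, Chi3l3 (42.4 to 7.84 FPKM), Ltf (24.1 to 9.01 FPKM), Ngp (450 to 182 FPKM) and Camp (84.2 to 37.8 FPKM). The list mean was -0.16, of opposite sign to its median. Mpo, the myeloperoxidase gene of immature granulocytes, was at 577 and 663 FPKM. Pan-leukocyte genes had a median of 0.40, above the random range (-0.42 to 0.18), with Tyrobp (19.8 to 43.9 FPKM) and Cd52 (15.8 to 33.3 FPKM) higher. Cd53 was at 6.10 and 11.5 FPKM, Fcer1g at 69.1 and 112 FPKM, and Ptprc, which encodes CD45, at 5.38 and 8.79 FPKM.

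Monocyte and macrophage genes (median 1.27) and haematopoietic stem and progenitor genes (median 1.06) lay above their random ranges. The monocyte and macrophage median lay inside its range with no filter (0.35) and at 5 FPKM or more (0.65). Of its 9 measured genes, 5 were at least 2-fold higher and none lower. In that list, C1qb (0.233 to 4.20 FPKM), Cd68 (3.14 to 13.2 FPKM) and C1qc (0.869 to 3.75 FPKM) were higher, and Cd14 was listed at 0 in the control and at 3.05 FPKM in the JAK2 V617F library. In the stem and progenitor list, 6 of 11 genes were at least 2-fold higher and none lower. Mecom, a stem cell transcription factor, was at 0.262 and 11.9 FPKM, Procr at 0.163 and 3.10 FPKM, and Hlf at 2.24 and 5.88 FPKM. Slamf1 was listed at 0 in the control and at 1.24 FPKM. Kit was at 69.0 and 48.5 FPKM. T and NK genes (median 1.31, 6 measured) also lay above, but with no filter on low values their median was 0.00 and inside its range. Of the 6, 4 were at least 2-fold higher and 1 lower. In that list, Lck (4.27 to 16.6 FPKM) and Nkg7 (27.3 to 76.6 FPKM) were higher. Cd4 was listed at 0 in the control and at 2.69 FPKM, and Trbc2 was at 4.98 FPKM in the control and listed at 0 in the JAK2 V617F library. Megakaryocyte genes (median 0.48) lay inside the range, and above it with no filter (0.47) or at 5 FPKM or more (0.97). In that list the platelet chemokine genes Pf4 and Ppbp were listed at 0 in the control and were at 24.1 and 9.76 FPKM in the JAK2 V617F library. Gp9 was at 2.43 and 5.69 FPKM. B cell genes (median 0.24) were inside, with Vpreb3 (8.54 to 22.5 FPKM) and Ms4a1 (0.268 to 1.94 FPKM) higher, Vpreb1 (7.84 to 3.17 FPKM) lower and Ighm at 62.6 and 118 FPKM. After rescaling to the same sum, Vpreb1 was within 2-fold and Ighm past it.

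Vascular mural transcripts were higher in the JAK2 V617F library, and endothelial transcripts did not shift as a group. Of 11 smooth muscle and pericyte genes, 5 were at least 2-fold higher and none lower, with a median log2 ratio of 0.67 above the random range (-0.46 to 0.36). They were Des (3.38 to 18.4 FPKM), Higd1b (1.17 to 6.32 FPKM), Acta2 (12.2 to 43.2 FPKM), the pericyte potassium channel gene Kcnj8 (7.60 to 24.2 FPKM) and its partner Abcc9 (11.5 to 29.6 FPKM). Rgs5 was at 115 and 183 FPKM. Endothelial genes had a median of 0.14, with Emcn (0.196 to 5.15 FPKM) and Erg (4.73 to 12.5 FPKM) higher and Plvap (8.48 to 1.89 FPKM) lower. Stab2 was listed at 0 in the control and at 1.07 FPKM, and Pecam1, which encodes the depleted marker CD31, was at 17.1 and 19.0 FPKM. Skeletal muscle genes had a median of -0.12. Of these, Acta1 (23.6 to 0.719 FPKM), Tnnt3 (4.03 to 0.545 FPKM) and Atp2a1 (4.40 to 1.57 FPKM) were lower, and Pvalb was listed at 0 in the control and at 1.11 FPKM. The call for Atp2a1 was lost after a median shift and after rescaling to the same sum.

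**Figure D2:**
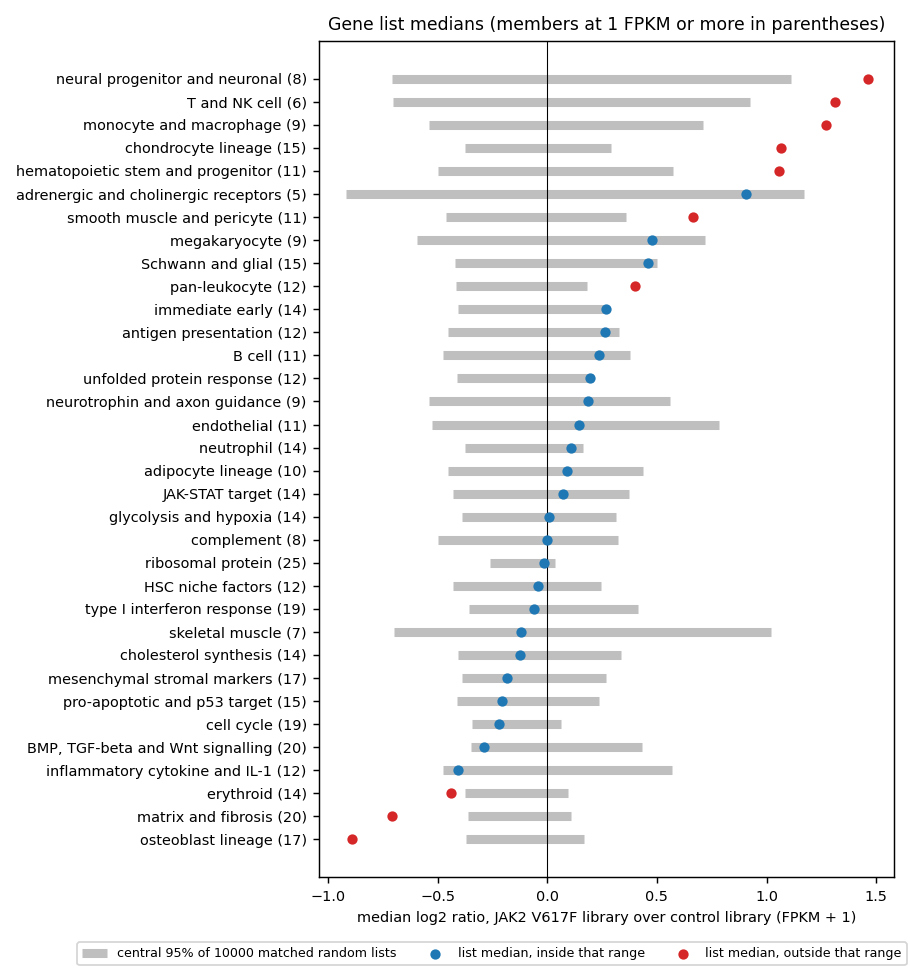
Median log2 ratio of FPKM + 1, JAK2 V617F library over control library, for the 34 gene lists with measured members, as points (red outside and blue inside the grey bar). Each grey bar is the central 95% of the medians of 10000 expression-matched random lists. Of the lists, 3 lie below their bar (erythroid, matrix, osteoblast) and 7 above.

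Across all 15425 rows at 1 FPKM or more, 2108 were at least 2-fold higher and 1743 at least 2-fold lower in the JAK2 V617F library. Among the 12477 protein-coding genes, 1247 were higher and 1086 lower, so that 53.5% of the called genes were higher. This share was 65.4% after both libraries were rescaled to the same sum, which raises the JAK2 V617F values by 0.18 on the log2 scale. It was 43.6% with a pseudocount of 5 (292 higher and 378 lower), 45.7% at 5 FPKM or more (641 and 761) and 50.1% with genes at 0 left out (971 and 969), so the balance between higher and lower has no stable direction. Dusp1, Gp9 and H2-Ab1 passed 2-fold under the 3 other scalings run for genes, Sema3a and Adra1b under a median shift and the rescaling, and Klf2 and Adra1d under the rescaling. A pseudocount of 5, which shrinks the ratios of low genes, ended the 2-fold call of 46 named genes. They were among 164 genes taken by parts of the naming rule other than the highest rows. Those 164 include genes within 2-fold on the deposited scale, such as Jak2 and most niche factors, which had no call to lose. The share of protein-coding genes past 2-fold depended on level. It was 36.1% at a mean of 0.5 to 5 FPKM (789 higher and 470 lower) and 8.7% at 20 to 50 FPKM (76 and 166). The balance between higher and lower thus turned with level. The 10 largest increases included Prg4, the cartilage gene Clec3a and the platelet gene Pf4. Clec3a, on chromosome 8 (114418086 to 114425846), was at 4.19 and 156 FPKM, a ratio of 36.1 with a counting interval of 19.4 to 75.9. Zmat4 (0.314 to 22.9 FPKM), Rogdi (0.350 to 20.9 FPKM) and Rabggtb (166 to 4006 FPKM) were also among them. Rabggtb shares its locus with Snord45b, a small RNA at 11064 FPKM in the control and 4791 FPKM in the JAK2 V617F library. Trnp1, the small RNA Scarna8 and the immunoglobulin segments Igkv6-32 and Iglv1 were listed at 0 in the control and were at 19.1, 171, 14.3 and 13.9 FPKM. The 10 largest decreases included Tmem38b (320 to 3.88 FPKM), Tead2 (82.2 to 2.40 FPKM), Thumpd3 (1143 to 52.1 FPKM), the microfibril gene Mfap5 (23.1 to 0.604 FPKM), Acta1, Tmem134 (81.6 to 5.16 FPKM) and Slc26a3 (12.9 to 0.174 FPKM). Ropn1, Ighv1-73 and Prg2, which encodes eosinophil major basic protein, were at 36.3, 24.2 and 22.2 FPKM in the control and listed at 0 in the JAK2 V617F library. For Prg2 these values stood for about 81 fragments against 0. Epx, another eosinophil gene, was low in both libraries, at 0.134 FPKM in the control and 0.297 FPKM in the JAK2 V617F library.

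The highest rows of both libraries were small RNAs, and most small RNA rows at 1 FPKM or more were listed at 0 in 1 library. All 16 rows among the 10 highest of either library were small RNAs, led by SNORD18 (45032 and 4824 FPKM) and Scarna9 (31366 and 32540 FPKM). Small RNA rows held 43.1% of the summed FPKM of the control library and 39.9% of that of the JAK2 V617F library. FPKM is scaled by transcript length, so these are not shares of the fragments. Of the 489 small RNA rows at 1 FPKM or more, 323 were listed at 0 in 1 of the libraries, against 393 of 12477 protein-coding genes. Of these 393, 276 were at 0 in the control library and 117 in the JAK2 V617F library. The estimated denominators were about 5500000 and 6360000 fragments. In the same order, 229 and 460 detected single-transcript genes lay below 3.5 estimated fragments. How far depth or amplification set the zeros was not tested. Differences of genes listed at 0 in the control library carry this limit. The correlation between the libraries across protein-coding genes was r = 0.909 on the log2(FPKM + 1) scale. Genes are not independent replicates, so this value describes likeness only.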

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

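With 1 library per genotype no replicate could be left out, and no setting here measures the spread between animals. No paired analysis was possible because each group has a single library. The restrictions to protein-coding genes, the other pool of random lists and the inclusion of shared rows were chosen after seeing the data. The counts of 2108 higher and 1743 lower moved by over 1.5 times with a pseudocount of 5 (610 and 633), at 5 FPKM or more (1024 and 1099), at a 4-fold threshold (529 and 408), among protein-coding genes (1247 and 1086) and among those with no small RNA in the locus (1165 and 1003). With genes at 0 left out, 1243 were higher. The osteoblast, chondrocyte and matrix medians stayed outside, and the niche and mesenchymal stromal medians inside, their random ranges under the 12 alternatives run for lists. The osteoblast median ran from -0.96 to -0.74, the chondrocyte median from 0.81 to 1.24, and the niche median from -0.10 to 0.13, so the niche list has no stable sign. Of 34 lists, 10 had medians of both signs over the settings. Of 403 list values under alternatives, 20 crossed the edge of the random range. The Schwann and glial median lay above it with a pseudocount of 0.1 (0.776), at 5 FPKM or more (0.745) and after rescaling without abundant classes (0.707). With no filter, the immediate early (0.268), neutrophil (0.2) and megakaryocyte (0.469) medians lay above, and the neuronal (0.358) and monocyte and macrophage (0.348) medians came inside. The T and NK median was 0.0 with no filter, so its sign and its place above the range were lost. At 5 FPKM or more, the unfolded protein response (0.216) and megakaryocyte (0.966) medians lay above, the inflammatory median (-0.772) lay below, and the monocyte and macrophage median (0.646) came inside. With genes at 0 left out, the neuronal median (0.241) came inside. With a pseudocount of 5, the unfolded protein response (0.187) and immediate early (0.237) medians lay above, and with 0.1 the BMP, TGF-beta and Wnt median (-0.414) lay below. Without shared markers and the gene of largest change, the immediate early (0.309) and neutrophil (0.2) medians lay above and the erythroid median (-0.391) came inside. The filter and zero settings alter which genes enter a list, and the cause was not tested further. The 4 scalings raised the JAK2 V617F library by 0.08 to 0.18 on the log2 scale. No named gene changed direction past 2-fold under the 5 settings run for genes, and of 820 gene values 58 lost and 28 gained the 2-fold call. Values of genes within 2-fold on the deposited scale are among the 820 and had no call to lose. Depth limits values near 1 FPKM, where a 2-kb transcript rests on about 10.1 fragments in the control and 11.6 in the JAK2 V617F library.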

Other observations

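The tests of articular, growth-plate and oligodendrocyte carry-over were set out before the values of those 3 added lists were seen, but after the genes that prompted them. The tests on haematopoietic dilution, scaling and Schwann cells were chosen after the result was seen. After a first run, the osteoblast and matrix lists, at first weighed as 1 pattern, were separated because the matrix difference was borderline. Also after the first run, a list was taken to argue against an explanation only where its median lay beyond the bound set for it by more than the SD of its members. By this later rule growth-plate and oligodendrocyte carry-over would both stay open, although both medians were under the bounds set before. The SD describes single genes and is not the error of a median. Growth-plate carry-over is weighed below against the chondrocyte median as well. Oligodendrocyte carry-over stays open, since only 6 genes of its list were detected. The genes named in the next paragraph were chosen after their values were seen.

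Further genes of connective tissue were higher in the JAK2 V617F library. Cytl1, a cartilage cytokine-like gene, was at 27.3 FPKM in the control and 394 FPKM in the JAK2 V617F library, and Cilp, of the cartilage intermediate layer, at 1.03 and 23.4 FPKM. Of 14 measured genes on the added articular and superficial-zone list, 5 were at least 2-fold higher and 1 was lower. Thbs4 (2.27 and 10.8 FPKM), Fmod (13.8 and 44.2 FPKM), Scrg1 (2.67 and 10.1 FPKM) and Dpt (11.5 and 27.4 FPKM) were among the higher, and Col14a1 (3.40 and 0.125 FPKM) was lower. Among granulocyte and mast cell genes outside the lists, the mast cell protease gene Cpa3 was at 1.12 and 14.2 FPKM and Alox15 at 10.7 and 0.165 FPKM. The transcription factor gene Prdm16, a relative of Mecom, was at 0.220 and 12.9 FPKM.

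The first pattern is the lower osteoblast-lineage expression. More blood cells in the pool would lower all stromal genes alike, yet the osteoblast median lay 0.71 below the mesenchymal stromal median (difference -0.71, permutation test over genes, two-sided p = 0.00088). The blood cell lists moved apart, with the erythroid median below 0 (-0.44). The neutrophil (0.11), pan-leukocyte (0.40), stem and progenitor (1.06) and monocyte and macrophage (1.27) medians lay above 0. Dilution by cells other than erythroid ones may thus still be a part of the decrease. The stromal list includes genes that other cells also express, such as Ebf1, and its members moved both ways (7 above 0 and 10 below). Pdgfra (-0.65) and Ebf3 (-0.67) fell and Mcam (1.56) rose. The difference from the osteoblast list therefore does not show how much of the decrease dilution could explain. Genes are not independent, so this p is a guide only, and for the matrix list the same difference was -0.52 with a permutation p of 0.0498, which the error of the permutation does not separate from the threshold, so dilution and a loss of matrix expression cannot be told apart there. The 4 scalings tried raised the JAK2 V617F library by only 0.08 to 0.18, and the highest osteoblast median under them was -0.736. Shifts of that size could not bring the median to 0, so they decide little. A single factor would move all genes alike, and 0 of 10000 matched random lists had a lower median, which argues against scaling alone. A smaller share of osteoblast-committed cells among the sorted cells, lower expression per cell, and chance differences between 2 pools may each explain the decrease. With 1 library per genotype no biological explanation was tested.

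The second pattern is the higher cartilage expression. Carry-over of growth-plate cartilage would raise its genes together. The added growth-plate list had a median log2 ratio of 0.08, against 1.07 for the chondrocyte list. Its members were both higher (Ucma, 5.38 and 12.0 FPKM) and lower (Col11a2, 59.2 and 26.0 FPKM). Its median thus lay below the chondrocyte median by more than the SD of its 14 detected members (0.82). That SD describes single genes, and the difference from the chondrocyte list was not tested. Growth-plate carry-over thus stays open, as a part or the whole of the rise. The added articular list had a median of 0.64, above 9992 of 10000 random lists, and did not differ detectably from the growth-plate list (difference 0.57, permutation test over genes, two-sided p = 0.427). A different amount of cartilage of either kind in the 2 dissections may thus be part of the difference, and a change in the differentiation of the nestin-GFP+ cells is as open.

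The third pattern is the higher Mbp (624 and 4872 FPKM) and Mobp (63.0 and 605.5 FPKM), 2 myelin genes. Oligodendrocytes carried over from the spinal canal would bring their other transcripts. The 6 detected genes of 15 on the added oligodendrocyte list had a median log2 ratio of 0.86 (SD 1.05) where Mbp was at 2.96, with 3 at least 2-fold higher and none lower, and the most abundant, Plekhb1, was at 22.4 and 111.5 FPKM, so such cells may be part of it. More Schwann cells as the whole cause are argued against by the glial list without Mbp, whose 14 measured genes had a median of 0.34 (SD 0.64). Transcripts of these loci in other cells and uneven amplification of little RNA were not tested and stay open.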
